A study of Mus musculus with 2 samples.

How the data were processed

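Total RNA of lung epithelial cells from a Mob1DKO and a WT preparation was amplified, labelled with Cy3 and hybridised to Agilent mouse arrays, per the labels' protocols. Each group holds 1 array, and both arrays lie on the same slide and were scanned once. The Mob1DKO array was grouped by its title and the WT array by its source name.

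The deposited scanner files give intensity values per spot on a linear scale. Per the file headers they were extracted with Agilent Feature Extraction 10.7.1.1 and a 1-colour gene expression protocol on a grid of build mm9, whereas the submitters' processing notes name version 9.5.1.1. The deposited processed signal is an intensity after background subtraction and detrending within the array, with low values set to a surrogate, and with no normalization between arrays. The deposited value table of the series holds intensity values whose making is not given in the sources used here. Its columns have the same sorted values within 0.1% and a median of 27.3 each. They matched a quantile normalization of the processed signal within 0.1% for 99.5% of Mob1DKO and 99.2% of WT probes, on a linear scale and without centring. Each column correlated with its own array at r = 0.9998 and 0.9995 on the log2 scale, across probes. A difference between these columns therefore has the direction of the labels.

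Spots of a probe were averaged on the linear scale, control spots were left out, and log2 of the processed signal was taken minus the array's 75th percentile over 55681 non-control probes. A probe was well above background where most of its spots carried the scanner software's flag for that. The local background had a median of 67 on both arrays. The 8 added spike-in transcripts well above background on both arrays were a median 2.50-fold brighter on the WT array (1.84-fold to 2.81-fold), while the 75th percentile of gene probes was 1.88-fold higher on the Mob1DKO array. Scaling therefore removes a difference in signal per spike-in of 4.69-fold, and the values say nothing about total RNA per cell.

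Probes were named through their RefSeq accession, without version, in a table of gene symbols on assembly GRCm38.p6, which was used only for names and for which genes neighbour each other. Of 55681 probes, 28685 carried a RefSeq accession, 27235 were named and 28446 stayed unnamed, which gave 20660 genes. For a gene with several probes, of which there were 5476, the value was that of the brightest probe over both arrays among those well above background on at least 1 array. Among 2868 genes with at least 2 probes well above background on both arrays, the median gap between the probes' differences was 0.20 and the 90th percentile 0.70. Of 93 called genes with several such probes, 66 had probes of 1 sign and 31 had every probe past 2-fold.

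A gene was called higher or lower when its log2 difference reached 1 in size and it was well above background on the brighter array. Where it was not well above background on the dimmer array, the fold is a bound. It sets the brighter value against the higher of the dim probe's own value and the lowest value among probes well above background on that array, which was −4.10 on the Mob1DKO array and −3.45 on the WT array. No fold is given where that bound is under 1. No tests were run, since 1 array per group leaves no residual degrees of freedom. For each of 33 gene lists, the median over measured members is given with its percentile among 10000 random lists of the same size drawn from 20 bins of mean level, as a description of these arrays. Lists with under 5 measured members have values only. Genes of a pathway share regulation, so random lists understate the spread of such medians: 16 of 32 lists fell outside the central 95%, where 1.6 would by chance.

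The lists, the calling rule, the alternatives and the rule for named genes were fixed before the data were examined. Named genes are Mob1a and Mob1b, the 12 largest increases and decreases among genes with a symbol that were well above background on both arrays and at or above the 75th percentile on the brighter one, and the 5 largest bounds each way. They also include up to 4 called members of each list by size, the 2 brightest members of main lists with under 2 called members, the 3 brightest members of lists of other cell types outside the central 95%, and a fixed set of sex-linked, Hippo and epithelial genes. Genes named beyond this rule are said to be.

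The alternatives were scaling on the median, on a housekeeping list, by quantiles, by loess (span 0.3) or not at all, and normexp background correction with an offset of 50. Scaling on the median, on the housekeeping list or not at all moves every gene alike. These settings therefore cannot change a list's percentile beyond the noise of random draws, although they count among the other settings below. Further alternatives were the series value table, other filters on background, removal of spots flagged as outliers, other rules for several probes, a floor and folds of 1.5 and 3. The scanner files used here hold no mean spot signal, so normexp was fitted to the median spot signal and its local background, which differs from the column first intended. In data simulated for 15099 genes from these arrays' levels and technical error, the 2-fold rule called 67 of 67 genes changed 3-fold, 66 of 66 changed 6-fold and 4 of 67 changed 1.5-fold. It called 34 of 14899 unchanged genes, all of them below the 75th percentile. The simulation treated every gene as well above background on both arrays, with technical error from probes that were. It therefore gives no rate of false calls for genes measured on 1 array, which made up 639 of the called genes against 372 on both arrays. For genes on both arrays it covers the technical error between spots only. It leaves out the difference between animals and between RNA preparations, so it gives no rate of false calls about genotype there either. Of 100 simulated lists of 20 unchanged genes, 5 fell outside the central 95%. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.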

Results

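RNA from mouse lung epithelial cells was measured on Agilent 1-colour oligonucleotide arrays, with 1 array for cells labelled Mob1DKO and 1 array for wild-type (WT) cells. Both labels give the strain C57BL/6 and an age of 10 weeks. The labels do not spell out Mob1DKO. It is read here, from knowledge of this mouse line, as loss of both Mob1a and Mob1b, which encode adaptor proteins that bind and activate the LATS kinases of the Hippo pathway. The comparison asks how gene expression in lung epithelial cells differs between these mice. Each array held 55681 non-control probes, of which 58.6% were well above background on the Mob1DKO array and 53.1% on the WT array. The 75th percentile of the processed signal was 291 on the Mob1DKO array and 155 on the WT array, and no spot was saturated. There were no replicates, so differences are given with their size and without p-values, and the number of arrays limits the precision. Levels and differences are on the log2 scale after subtracting each array's 75th percentile, and differences are Mob1DKO minus WT. Probes printed at 10 spots gave the technical error of a single-spot difference, with an SD of 0.36 below the 75th percentile and 0.089 above it. This error leaves out the difference between animals and between RNA preparations.

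The targeted genes were examined first. Mob1b was 4.0-fold lower on the Mob1DKO array, at −2.98 against −0.98, a difference of −2.00 on a probe with a technical SD of 0.36. A second Mob1b probe differed by −2.70. The single Mob1a probe gave −2.49 on the Mob1DKO array and −2.56 on the WT array, a difference of 0.07 that lay within its technical SD of 0.36. The position of these probes relative to the deleted parts of the genes is not given in the sources used here, so the Mob1a value checks nothing about a deletion of Mob1a. With a model-based background correction of the median spot signal, with an offset, in place of the processed signal, Mob1b differed by −1.13 and Mob1a by −0.42. The offset by itself moves the differences of faint probes such as these. Of the 7 measured MOB family genes, Mob1b passed the 2-fold rule and the other members differed by −0.59 (Mob3b) to 0.27 (Mob4), with a list median of −0.01.

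Genes of the mucus-producing goblet cells were lower on the Mob1DKO array. Of 11 measured goblet cell genes, 9 were at least 2-fold lower and none was higher, with a list median of −1.60. Clca1, a secreted regulator of mucus, was 59.9-fold lower. Tff2, a trefoil peptide, was 5.25-fold lower, the gel-forming mucin Muc5b 3.37-fold lower and the secreted airway protein Bpifb1 3.23-fold lower. Among basal cell genes, the keratins Krt5, Krt17 and Krt15 were 7.43-fold, 5.94-fold and 2.96-fold lower. Targets of YAP and TAZ, the transcriptional co-activators restrained by the Hippo pathway, had a median of 0.20, and 1 of 25 measured members, Igfbp3, passed the 2-fold rule, though not under the model-based background correction.

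The other called goblet cell genes, named here after their values were seen, were Agr2 (3.11-fold lower), Fcgbp (3.03-fold), Spdef (2.48-fold), Muc5ac (2.40-fold) and Tff1 (2.40-fold). Spdef encodes a transcription factor of goblet cell differentiation, and Muc5ac encodes a gel-forming mucin. The goblet median lay below those of all 10000 random lists matched on size and mean level, as a description of these arrays. In the basal cell and hemidesmosome list, 4 of 16 measured genes were lower and none was higher, with a median of −0.14 at the 2.26th percentile of matched lists, outside the central 95% under 8 of 14 other settings. The fourth called gene was the water channel Aqp3, at 2.06-fold lower, or −0.84 under the model-based background correction. Krt5 had a second probe that was not well above background on either array. The hemidesmosome collagen Col17a1 was not well above background on either array.

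**Figure D1:**
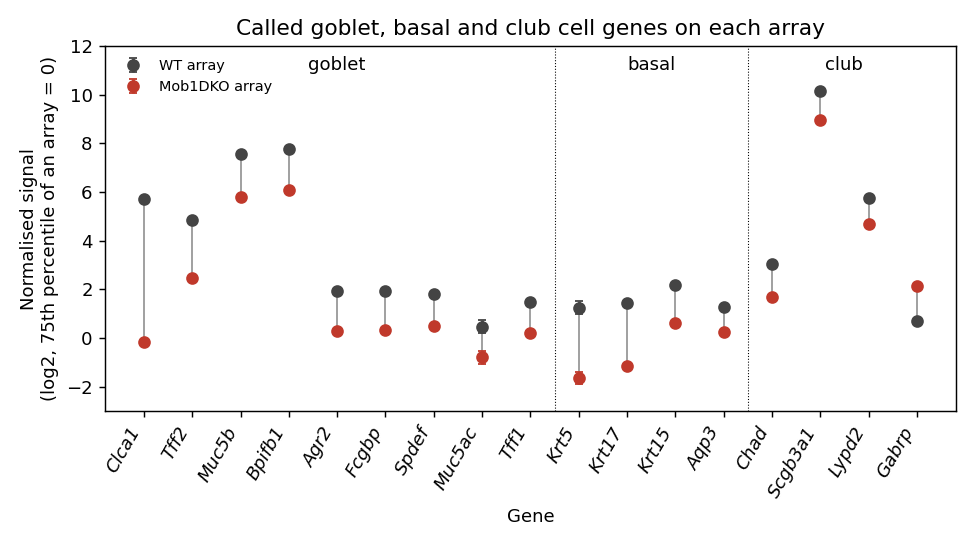
Normalised signal (y axis, log2, with each array's 75th percentile at 0) of the called goblet, basal and club cell genes (x axis) on the WT array (dark) and the Mob1DKO array (red), with bars for 1 technical SD of a single spot's value. All 9 goblet and all 4 basal genes lie lower on the Mob1DKO array, from Clca1 at 59.9-fold to Aqp3 at 2.06-fold, and the club cell gene Gabrp lies higher.

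Club cell genes were lower as a list, with a median of −0.26 at the 0.06th percentile of matched lists. Of 18 measured members, 3 were lower and 1 was higher. Chad was 2.59-fold, the secretoglobin Scgb3a1 2.28-fold and Lypd2 2.09-fold lower, of which only Chad stayed past 2-fold under that background correction, while Gabrp, a GABA receptor subunit, was 2.69-fold higher. Scgb1a1, the main secretory product of club cells, differed by −0.84 and was not called. Relative to the median of all genes, it ranged over the settings from −0.86 to −0.17. Its probe was among the 20 brightest genes, at a mean level of 10 or more, and all 20 differed in the same direction, with a median of −0.59. None of 18 measured ciliated cell genes was called. Their median was −0.03 at the 23.4th percentile, and the tubulin Tubb4b differed by −0.04 and Mcidas by 0.02.

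Alveolar genes differed little. Of 23 measured alveolar type 2 genes, 1 was higher and none was lower, with a median of −0.13 at the 2.35th percentile that turned to 0.070 under the model-based background correction and stayed outside the central 95% under 8 of 14 other settings. The called member was Rab27a, a GTPase of secretory vesicle transport, at 2.04-fold higher, or 0.75 under that correction. Surfactant protein C (Sftpc) differed by −0.78 and surfactant protein B (Sftpb) by −0.31, and Sftpc also belonged to the 20 brightest genes. A second, dimmer Sftpb probe, well above background on both arrays, differed by 0.02. Relative to the median of all genes, Sftpc ranged over the settings from −0.81 to −0.025 and Sftpb from −0.33 to 0.028. Of 18 measured alveolar type 1 genes, 1 was higher and none was lower, with a median of 0.14 at the 97.6th percentile, outside the central 95% under 10 of 14 other settings. The called member was the basement membrane collagen Col4a3 at 2.46-fold higher (0.52 under that correction), and Gprc5a and Lmo7 differed by 0.04 and 0.07. In the surfactant lipid synthesis list, 1 of 26 measured genes, Pcyt1b, was at least 9.48-fold lower, and the median was −0.05 at the 14.7th percentile. None of 19 measured genes of the Krt8-high transitional state was called, with a median of −0.07 at the 16.5th percentile. Its brightest members Krt18 and Lgals3 differed by −0.13 and 0.06.

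YAP/TAZ targets lay slightly higher on the Mob1DKO array. None of 20 measured Hippo pathway components was called, and their median was 0.16 at the 97.9th percentile, outside the central 95% under 9 of 14 other settings. Yap1 differed by 0.00, Wwtr1 (which encodes TAZ) by 0.36, Rassf1 by 0.43 and Taok1 by −0.02. Of the 25 measured YAP/TAZ targets, 20 had a difference above 0, and the median of 0.20 lay at the 99.9th percentile of matched lists. The called target Igfbp3, an insulin-like growth factor binding protein, was 2.18-fold higher (1.13), but differed by 0.22 under the model-based background correction. Ccn2 and Ccn1, matricellular proteins widely used as YAP reporters, differed by 0.61 and 0.31, F3 by 0.17 and Gadd45b by 0.29. Ankrd1 was well above background on the Mob1DKO array only, at least 1.54-fold higher there, but differed by −0.26 under the background correction. In the TGF-beta and BMP list, 1 of 27 measured genes was higher and none was lower, with a median of 0.12 at the 97.1st percentile. The called member, Bmp7, was at least 1.95-fold higher but turned to −0.11 under the model-based background correction, and Thbs1 and Tgfb2 differed by 0.10 and 0.02. Among 27 measured cell cycle genes, Cdk1 was 19.5-fold lower and the ribonucleotide reductase subunit Rrm2 2.02-fold higher (0.66 under the background correction). The cell cycle median was −0.16 at the 1.78th percentile, outside the central 95% under 13 of 14 other settings. The Cdk1 value rested on 1 of 3 probes, since the others were not well above background on either array.

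**Figure D2:**
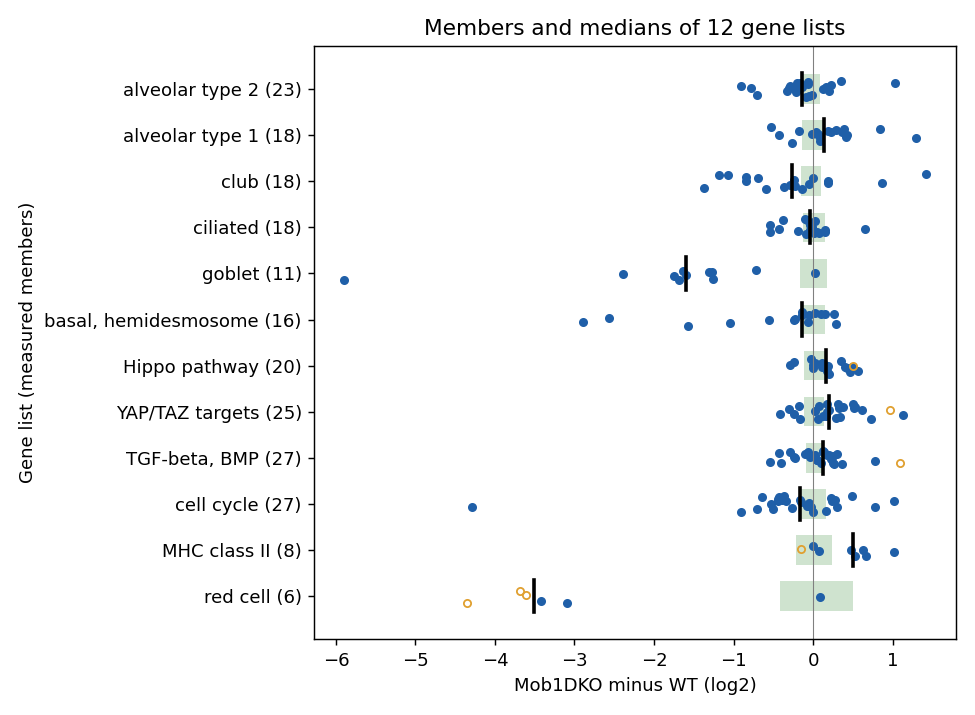
Log2 difference, Mob1DKO minus WT (x axis), of each measured member of 12 gene lists (y axis, number measured in brackets). Filled points were well above background on both arrays and open points on 1 array, black bars are list medians and green bands hold the central 95% of 10000 matched random lists. The goblet median stands at −1.60 and the red cell median at −3.51, while the ciliated median of −0.03 lies inside its band.

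Across all genes, the decreases measured on both arrays were led by Clca1, Cdk1 and Chil3, a chitinase-like protein of macrophages and airway epithelium that was 17.8-fold lower. They were followed by the lysosomal phosphatase Acp2 (10.8-fold), the alpha globins Hba-a2 (a log2 difference of −3.42) and Hba-a1 (8.57-fold), the glutathione transferase Gstm6 (8.74-fold), Mrgprf (8.58-fold), Fbxw13 (8.51-fold), Iqcf1 (7.66-fold), Krt5 and the interferon-induced Oas2 (7.41-fold). All 3 Gstm6 probes were at least 2-fold lower, 1 of them by its bound, whereas a second Acp2 probe differed by −0.61. The increases were led by the serine protease Prss21 at 66.9-fold and Rnf225 at 27.6-fold. They were followed by Abca17 (12.2-fold), the prostacyclin receptor Ptgir (10.1-fold), Prdm6 (6.78-fold), Bbs10 (5.49-fold), Arfgef3 (4.48-fold), Galnt10 (4.2-fold), Ap2b1 (4.13-fold), Tmem44 (4.03-fold), Psap (3.99-fold) and the protease-activated receptor F2rl1 (3.83-fold, or 0.74 under the background correction). All 3 Tmem44 probes were at least 2-fold higher, 2 of them with a WT value not well above background. A second Abca17 probe differed by 0.87, and a second Bbs10 probe by −0.043, against the direction of the first. The WT values of Prss21 (−3.38), Abca17 (−3.27), Ptgir (−3.17) and Rnf225 (−3.04) lay close to −3.45, the lowest WT value well above background. Their folds therefore rest on faint WT signals. Relative to the median of all genes, differences shrank under other settings to as little as 3.63 for Prss21, 2.86 for Rnf225, 1.66 for Ptgir and 1.35 for Prdm6. For Cdk1 and Chil3 they shrank to −2.41 and −2.54, while Clca1 stayed between −5.95 and −5.34.

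Genes well above background on 1 array only have a bound in place of a fold. The largest bounds for Mob1DKO were at least 29.6-fold for Eif2s3y, 22.7-fold for Ddx3y, 22.6-fold for Gucy2e, 21.3-fold for Sly and 17.4-fold for Hdgfl1. The largest bounds for WT were at least 23.5-fold for Olfr1261, 23.2-fold for Cyp8b1, 22.0-fold for Olfr827, 21.6-fold for Ces2c and 21.3-fold for Chil4, a second chitinase-like gene. A second Ces2c probe, well above background on the WT array, differed by −0.76. The Gucy2e bound rested on 1 of 3 probes, since the others were not well above background on either array. Eif2s3y, Ddx3y and Sly lie on the Y chromosome. The Y-linked Uty was at least 1.13-fold higher (0.044 under the background correction), and Kdm5d was not well above background on either array. Xist, the RNA that silences an X chromosome in females, was 4.90-fold lower on the Mob1DKO array, and its second probe differed by −2.22.

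Markers of other cell types also moved. Of 6 measured red cell genes, 5 were lower, with a median of −3.51, or −2.82 with one-array genes at their bounds, below all matched lists. All 5 were related globin genes, which are not independent markers. The 1 other measured member had a difference above 0 and was not called. The beta globin Hbb-bt was at least 19.4-fold lower, Hbb-b2 at least 5.78-fold and Hbb-bs at least 3.23-fold. The median of 20 measured fibroblast, smooth muscle and mesothelial genes was −0.26 at the 0.04th percentile, with the pericyte gene Cspg4 2.57-fold lower, Lum at least 2.22-fold higher, both under 2-fold with the background correction, and Dcn, Msln and Col1a2 at 0.18, −0.25 and −0.27. None of 10 measured endothelial genes was called, and their median was −0.29 at the 1.45th percentile, outside the central 95% under 11 of 13 other settings. Kdr, Esam and Egfl7 differed by −0.60, −0.15 and 0.53, and a second Kdr probe by 0.05. The median of 9 measured pan-leukocyte genes was 0.06 at the 60th percentile, and that of 24 genes shared by lung epithelial types was 0.02 at the 64.4th percentile.

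**Figure D3:**
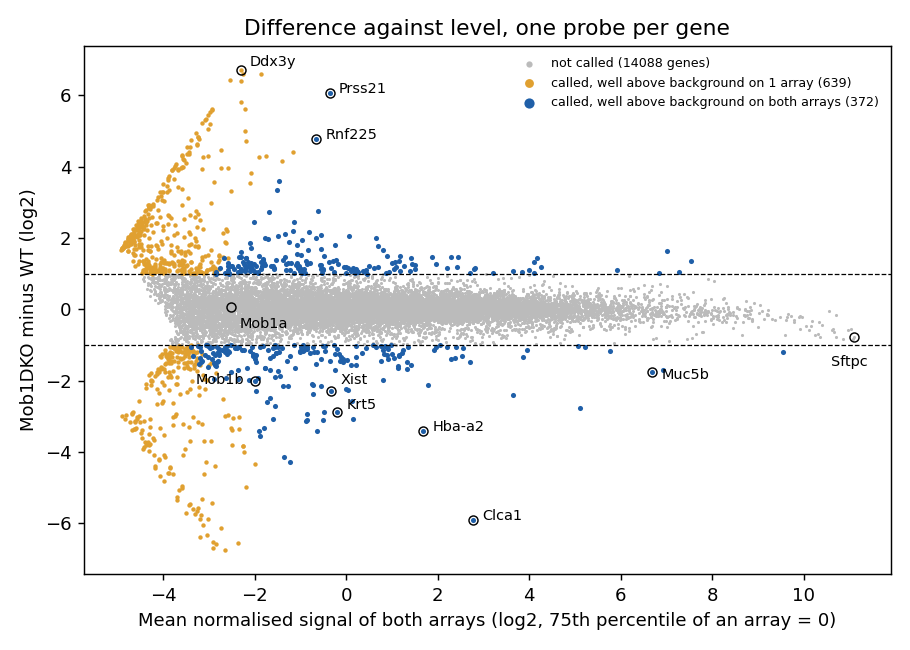
Log2 difference, Mob1DKO minus WT (y axis), against the mean normalised level of both arrays (x axis, log2), 1 point per gene, with dashed lines at 2-fold. Blue points are the 372 called genes well above background on both arrays, orange points the 639 called genes well above background on 1 array, and grey points the remaining genes. Among named genes well above background on both arrays, Clca1 stands apart in the decreases and Prss21 in the increases. Some one-array genes, such as Cyp8b1 and Ddx3y, lie further from 0. The brightest genes, such as Sftpc, bend below 0.

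Of 15099 genes well above background on at least 1 array, 572 were called higher and 439 called lower on the Mob1DKO array. Among genes well above background on both arrays, 174 were higher and 198 lower. The remaining 398 higher and 241 lower genes were measured on 1 array, and the bound reached 2-fold for 117 and 185 of them. The others of these may differ by less than 2-fold. The excess of higher over lower calls thus came from one-array genes and was absent among genes measured on both arrays and among bounds of 2-fold. The middle of all differences lay between −0.18 and 0.22 (interquartile range), and levels correlated across genes with r = 0.987, where genes are not independent replicates. Under the model-based background correction 99 genes were higher and 173 lower, and they included 88 of the 572 higher and 172 of the 439 lower genes. The offset in that correction by itself shrinks the differences of faint genes and shifts them toward WT. Sex-linked genes differed between the arrays together with the genotype labels, and no value here separates the sex of the animals from genotype.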

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

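The test of airway cell share, the entry for sex beside the goblet genes, and the test of faint genes reported under other observations were chosen after the results were seen, as were a condition that leaves a test undecided when fewer than 3 in 4 members of its list share a sign and the demand that the median's whole interval pass the bound. These changes moved the type 2 and red cell tests from counting against their explanations to undecided. Probes without a gene name here were left out of every count of genes. Of 28446 such probes, 13900 were well above background on at least 1 array. Of these, 1214 passed the 2-fold rule as brighter on the Mob1DKO array and 693 on the WT array, with no bounds computed for those faint on the other array. They were flagged because they hold signal that the comparison of named genes does not use.

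The goblet cell decrease was weighed against 3 explanations. An even loss of all airway cells in the Mob1DKO preparation would lower ciliated cell genes by as much. The ciliated median exceeded the goblet median by 1.56 (95% bootstrap interval over members 1.17 to 1.73), which argues against such an even loss as the whole cause. Both medians were known when this comparison was chosen, and its interval is over genes, not animals or preparations. It does not test a lower share of only some airway cells or airway regions, which stays open. A type 2 cytokine response in the WT mouse may have raised goblet genes there, yet 11 measured response genes of a list of 14 had a median of 0.23 (−0.29 to 0.48), past the bound of −0.5 fixed beforehand as counting against it. Of these genes 4 lay below 0, among them Itln1, at least 3.95-fold lower, and Retnla, the brightest member, which differed by −0.84. Arg1 was 2.63-fold and Ccl11 at least 2.17-fold higher, both from faint signals. The type 2 explanation is left open because of the added condition, because members went both ways, and because that list left out Clca1, Chil3 and Chil4, type 2 targets already seen to be lower. A difference in sex between the mice stays open too, since the Xist difference of −2.29 comes with the genotype labels. An effect of the Mob1DKO genotype is also open and untested, because 1 array per group cannot separate it from these.

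The sex-linked pattern was put to genes not seen before. If the mice differed in sex, X-linked genes that escape X inactivation should be slightly lower on the Mob1DKO array. Ddx3x, Kdm6a, Kdm5c and Eif2s3x differed by −0.23, −0.21, −0.30 and −0.38, a median of −0.27. This is the direction that a Mob1DKO preparation mainly from a male and a WT preparation mainly from a female would give. With 4 genes, the bootstrap interval (−0.38 to −0.21) only spans the lowest to the highest value. The limit of 5 measured members was not applied to this test. Xist was well above background on both arrays, so a mixture of animals is not excluded.

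The globin decrease may come from fewer red cells in the Mob1DKO preparation. Of 14 further red cell genes, 8 were measured, with a median of −0.0063 (−0.53 to 0.77) and 4 below 0, and the called ones went apart, Rhag at least 9.45-fold higher and Trim58 at least 2.09-fold lower. The median passed the bound of −0.5 fixed beforehand as counting against this, but its interval reached that bound and the added condition also applied, so the test is left undecided. Globin transcripts in epithelial cells themselves remain open and were not tested.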

How the results depend on the processing

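Each value was recomputed under up to 14 other settings, all fixed beforehand except the spot signal column used for normexp, and the counts also at folds of 1.5 and 3. Of 16 lists outside the central 95% of matched lists, 6 stayed outside on the same side under every setting that gave a value: goblet, club, mesenchymal and red cell genes (lower), and YAP/TAZ targets and MHC class II genes (higher). Under median, housekeeping and no scaling, percentiles differed only through new random draws. Such draws alone put alveolar type 1 genes inside under median scaling (97.3rd percentile) and basal genes under housekeeping scaling (2.55th). The series value table nearly repeats quantile normalization. The alveolar type 2 list was inside under quantile normalization, the series value table, loess and normexp, among others. Relative to the median of all genes, 13 of the 16 lists kept their direction under every setting, and the alveolar type 2, cytokine and neuroendocrine lists turned. Of 572 higher and 439 lower genes, 566 and 437 were also called under quantile normalization and in the series value table, 570 and 368 under loess, and 88 and 172 under normexp. The cause of the changes listed here was not tested, except where the setting itself makes them. Normexp changed the background method, the offset and the spot signal at once, and the share of its changes due to each was not computed. Its offset of 50 exceeds the median processed signal of 35.8 on the Mob1DKO array and 18.9 on the WT array. Such an offset by itself shrinks the differences of faint genes. After scaling it also lowers Mob1DKO minus WT for them, because the WT array has the lower 75th percentile. Normexp values of faint genes, Mob1a among them, therefore mix this effect with the correction of background. Without scaling, every difference shifts up by the 0.91 between the arrays' 75th percentiles. Then 6149 genes were higher and 174 lower (97.2% higher, against 56.6% in the main setting), Mob1a differed by 0.98 and Mob1b by −1.09. By this shift alone 13 list medians went from below to above 0. Of the lists outside the central 95%, these were alveolar type 2 0.78, club 0.65, basal and hemidesmosome 0.77, cell cycle 0.75, endothelial 0.62 and mesenchymal 0.65. Of the lists inside it, they were ciliated 0.87, transitional state 0.84, extracellular matrix 0.84, surfactant lipid 0.86, lymphocyte 0.88, housekeeping 0.79 and MOB family 0.90. The medians that kept their sign became Hippo components 1.07, YAP/TAZ targets 1.11, alveolar type 1 1.05, goblet −0.69, epithelial-mesenchymal transition 0.999, TGF-beta and BMP 1.03, cytokine 1.13, interferon 1.01, MHC class II 1.41, apoptosis and senescence 1.09, xenobiotic 0.95, Notch, Wnt and FGF 1.03, immediate early 1.03, macrophage 1.098, neutrophil 0.96, pan-leukocyte 0.97, red cell −2.60, neuroendocrine 1.41 and pan-epithelial 0.93. Scaling on the housekeeping list shifts all genes by 0.12, with 690 higher and 370 lower (65.1% higher), and gave medians of Hippo components 0.28, YAP/TAZ targets 0.32, alveolar type 2 −0.015, alveolar type 1 0.26, ciliated 0.082, transitional state 0.044, epithelial-mesenchymal transition 0.21, TGF-beta and BMP 0.24, extracellular matrix 0.044, surfactant lipid 0.063, apoptosis and senescence 0.30, xenobiotic 0.15, Notch, Wnt and FGF 0.24, immediate early 0.23, pan-epithelial 0.14 and housekeeping 0, the last by construction. The ciliated, transitional, extracellular matrix and surfactant lipid medians thereby changed sign, as did lymphocyte (0.086) and MOB family (0.10). Quantile normalization gave medians of YAP/TAZ targets 0.31, alveolar type 2 −0.028, transitional state −0.0031 and pan-epithelial 0.092, the series value table YAP/TAZ targets 0.29, alveolar type 2 −0.029, transitional state −0.0039 and pan-epithelial 0.090, and loess YAP/TAZ targets 0.32, alveolar type 2 −0.020, transitional state 0.055 and pan-epithelial 0.11. Scgb3a1 was under 2-fold in all of these (−0.87, −0.84 and −0.95), and Lypd2 (−0.95) and Aqp3 (−0.93) on the housekeeping list. Loess called 719 genes higher and 369 lower (66.1% higher). Under normexp 99 genes were higher and 173 lower (36.4% higher), Mob1a differed by −0.42 and Mob1b by −1.13. There 10 list medians changed sign. Of the lists outside the central 95%, these were alveolar type 2 0.070 and neuroendocrine −0.20. Of the lists inside it, they were ciliated 0.10, transitional state 0.068, surfactant lipid 0.10, macrophage −0.23, lymphocyte 0.0050, neutrophil −0.44, pan-leukocyte −0.26 and housekeeping 0.066. Medians that moved with their sign kept were alveolar type 1 0.32, goblet −1.25, cytokine 0.0058, xenobiotic 0.24, immediate early 0.27, red cell −1.79 and pan-epithelial 0.22, and MOB family went to −0.37. Of 75 called named genes, 26 were under 2-fold there: F2rl1, Igfbp3, Rab27a, Col4a3, Scgb3a1, Lypd2, Aqp3, Cdh2, Rrm2, Lum, Postn, Isg15, Spry2, Cspg4, Fabp4, Cd79a, Jchain, Resp18, Uty and those that turned. Ankrd1, not called, turned to −0.26. The called ones that turned were Bmp7 −0.11, S100a9 −0.53, S100a8 −0.39, Cyp1a1 −0.022, Ear2 −0.44, Ccr2 −0.49 and Chgb −0.018. Requiring both arrays well above background left 174 higher and 198 lower genes, and requiring the brighter array at its 75th percentile left 97 and 98, with a macrophage median of −0.10. Both settings admit fewer genes. Without a filter 807 genes were higher and 1208 lower, with medians of goblet −1.31, cell cycle −0.30, endothelial −0.53, lymphocyte −0.38 and neuroendocrine 0.29. A floor at the lowest signal above background gave 294 higher and 286 lower genes and medians of cytokine 0 and red cell −2.49. This floor was the WT array's −3.45 applied to both arrays, whereas the bounds use each array's own lowest value. It is therefore stricter than the bounds for genes lower on the Mob1DKO array. At 1.5-fold, 1220 genes were higher and 1019 lower, and at 3-fold, 283 and 219. With the median over a gene's probes, the YAP/TAZ target median became 0.29 and Csf1 turned to −0.10. With the probe of smallest difference, medians became TGF-beta and BMP 0.053 and housekeeping −0.031, Bbs10 turned to −0.043 and Csf1 to −0.10. Leaving out spots flagged as outliers moved none of these values past its technical or bootstrap error, and neither did median scaling, though the pan-leukocyte median was −0.093 without those spots. Of 1422 recomputed differences of named genes, 10 turned for genes called in the main setting. Of the others, 1094 moved by less than the technical SD and 318 by more. Sign changes of genes not called, such as Ankrd1, are counted within these and not as turned. Part of this tally was fixed in advance, so it does not measure robustness. The filters on background and level only change which genes are admitted, so every gene value under them counts as moved by less. Median, housekeeping and no scaling shift all genes by the same amount, so each label there depends only on a gene's technical SD. The series value table adds little beyond quantile normalization.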

Other observations

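Among immune and signalling lists, the largest list median was that of the MHC class II genes. Of 8 measured MHC class II genes, 1 was at least 2-fold higher on the Mob1DKO array, H2-DMb1 at 2.03-fold, and the median was 0.50 at the 99.98th percentile of matched random lists. Of 23 measured cytokine and chemokine genes, 5 were higher and none was lower, with a median of 0.22 at the 99.3rd percentile that fell to 0 with one-array genes at their bounds and stayed outside the central 95% under 10 of 14 other settings. The called members include S100a8 and S100a9, which came from faint signals without a fold and turned to −0.39 and −0.53 under normexp. The monocyte attractant Ccl2 was 2.75-fold higher, and Csf1 was 2.42-fold higher on 1 probe and differed by −0.37 and −0.10 on the others. Of 22 interferon-stimulated genes, Isg15 was 2.20-fold higher on its brighter probe and at least 2-fold higher on both (0.98 under normexp), Oas2 was lower, and the median was 0.10 at the 82nd percentile. The p53, apoptosis and senescence list had a median of 0.18 at the 99.1st percentile with Igfbp3, which lost its call under normexp, as its only called member among 20, and the immediate early and heat shock list had a median of 0.12 at the 98.9th percentile with none called among 21.

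Among 22 measured xenobiotic and antioxidant genes, the cytochrome Cyp1b1 was 2.20-fold higher and Cyp1a1 at least 1.52-fold higher but −0.022 under normexp, with a median of 0.04 at the 79th percentile. Of 26 Notch, Wnt, hedgehog and FGF pathway genes, Spry2, a feedback inhibitor of FGF signalling, was 3.51-fold higher (0.96 under normexp), and the median was 0.12 at the 91.7th percentile. In the epithelial-mesenchymal transition list, Cdh2 (N-cadherin) was the only called member among 18, at 2.61-fold higher (0.56 under normexp), with a second probe at 0.84 and a median of 0.09 at the 82.7th percentile. Of 20 extracellular matrix genes, Lum was higher and Postn 2.06-fold lower (0.058 and −0.70 under normexp), with a median of −0.07 at the 9.8th percentile. Of 11 neuroendocrine and tuft cell genes, Resp18 was 2.77-fold and Chgb at least 2.06-fold higher (0.28 and −0.018 under normexp), Syp, Uchl1 and Dclk1 differed by −0.68, 0.71 and −0.16, and the median was 0.50 at the 99.85th percentile but −0.20 under normexp. Of 13 measured macrophage genes, Fabp4 was 2.14-fold higher (0.20 under normexp), Ear2 and Ccr2 were called higher on the Mob1DKO array with no fold and turned under normexp, Chil3 was lower, and the median was 0.19 at the 86th percentile. Lymphocyte genes had a median of −0.03 at the 29.7th percentile over 11 members, with Cd79a at least 3.38-fold and Jchain at least 1.98-fold higher (0.20 and 0.16 under normexp). Neutrophil and mast cell genes had a median of 0.05 at the 49.9th percentile over 6 members, with S100a8 and S100a9 called higher from faint signals, without a fold and turned under normexp. The housekeeping list had a median of −0.12 at the 6.95th percentile with none called among 17.

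The test of faint genes below was chosen after the count was seen, and the genes beside Mob1b were named after their values were seen. A hypothesis from the knockout design was that DNA of another strain, carried along beside the targeted genes, or another local effect would show as called genes next to them. Of the 50 measured genes nearest to Mob1b, 14 were called (9 higher, 5 lower), against a median of 3 over 14085 windows of that size, and 0.504% of windows held as many or more. The 5 measured genes that follow Mob1b on one side were all called: Dck was 2.09-fold lower, Slc4a4 2.12-fold and Gc 2.43-fold higher with signal on both arrays, and Npffr2 and Gm7056 were at least 1.87-fold and 3.06-fold higher with signal on the Mob1DKO array only. Faint genes are called more often, but level alone does not account for the count. In 10000 sets of 50 genes matched on level, the mean was 5.84, and the observed count stood above 100% of them. Genes of these sets were drawn without regard to position, so the sets do not test faint related genes that lie in clusters. Of the 50 genes nearest to Mob1a, 7 were called (2 higher, 5 lower, 5 of them with signal on both arrays), more than in 92.7% of windows and in 98.7% of the sets matched on level, whose mean was 2.83. A local effect around Mob1b may therefore be present, but 8 of its 14 called genes were measured on 1 array only, and a passenger segment, a local effect of the targeted allele and clusters of related genes remain open.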
